A study of Mus musculus with 29 samples.

How the data were processed

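RNA was measured in 29 libraries of mouse heart in 8 groups, 4 genotypes in unstressed hearts or 4 weeks after transverse aortic constriction (TAC). Per the labels' protocols, ventricular apexes were frozen, RNA was taken up in Trizol and polyadenylated RNA was made into non-strand-specific single-end libraries, while the tissue label names the whole heart. The deposited values are raw counts per gene symbol, made by the authors with mm10, TopHat2 2.0.10, Bowtie2 and HTSeq, per the submitters' processing notes, which also name DESeq and edgeR. The role and parameters of each tool and the gene annotation used for counting are not given in the sources used here. Each library's file listed 23420 genes and 5 totals of reads outside genes, which were left out of library sizes. Reads that fell on more than 1 gene made up 0.78% to 0.94% of the reads, and those aligned to more than 1 place 8.01% to 14.2%. HTSeq lists such reads apart from genes, so genes with near-identical copies are undercounted, and without strand the reads of overlapping genes on opposite strands are counted together or set aside. The deposited table of the whole series shared 23391 gene names with the library files, with identical counts in all 29 libraries, and 29 genes were missing from it.

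Counts assigned to genes ranged from 10523709 to 17314739 per library. Groups came from the labels, and each library counted as 1 sample. The labels do not state the link between libraries and animals beyond 1 title each, so the p-values measure the spread between these libraries. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion and TMM normalization. It had a filter on low counts by group that left 13765 genes, group means and the sex label as terms, and all 29 libraries in a single model with 20 residual degrees of freedom. Benjamini-Hochberg (BH) adjustment was at 0.05 within each of 15 comparisons. These were TAC against unstressed in each genotype, each ablation against wild type in each condition, the difference of each TAC effect from that of wild type (interaction), and the departure of the combined ablation from the sum of the single ablations on the log scale. A called gene has an adjusted p below 0.05, and log2 fold changes are given ± SE and CPM ± SD. Because TAC included hearts labelled female and the unstressed arm did not, the sex term rests on the TAC libraries.

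Of 31 gene lists, 18 of pathways and 13 of cell types and sex, 30 had measured members and were tested with camera at a preset correlation between genes of 0.01, with BH over the lists of a comparison, again with an estimated correlation, and with fry. Fry tests whether a list's genes move, on balance, in a single direction and does not set them against other genes. Camera made 98 list calls over the 15 comparisons, of which 7 held with an estimated correlation, and those are named in the text. Named genes were Prkcd and Prkce, up to 8 called genes per direction with the largest fold change, a mean log2 CPM of at least 2 and no overlap between the 2 groups. Added were up to 4 members with the smallest adjusted p of each list described, and 15 cardiac genes fixed in advance, of which the text names a subset. Results of some genes are not reported here. The comparisons, lists, naming rule and the settings varied were chosen before the data were examined. Gene positions are those of RefSeq for GRCm38.p6, with 13715 of 13765 genes matched, and overlaps of exons were taken from GENCODE vM21.

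Alternatives were RLE normalization, no filter on low counts, no sex term, only libraries labelled male, the replicate number as a block, only the groups compared, DESeq2 1.42.0, each library left out in turn, and for correlations of TAC fold changes only genes with a mean log2 CPM of at least 2. After seeing the data, 3 more were added: a score of Y-linked transcripts for the sex label, leaving out both the library labelled combined ablation, TAC, replicate 2 and wild-type TAC replicate 2, and this without the sex term. On simulated data with the design of the TAC effect in wild type and 200 changed genes among 13598, 61.2%, 88.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 9 false among 171 calls, and no gene was called where none was changed. Simulated genes varied independently, with a spread set by expression level alone, a single baseline for all groups and no sex effect. The rates hold for such data only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.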

Results

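Polyadenylated RNA from the ventricular apex of mouse hearts (C57BL/6J, labelled 12 weeks old) was sequenced as 29 non-strand-specific single-end libraries and deposited as read counts per gene symbol. The series crossed 4 genotypes with 2 conditions: wild type, postnatal cardiac ablation of PKCδ, germline knockout of PKCε, and both together, each in unstressed hearts or 4 weeks after transverse aortic constriction (TAC), a surgical narrowing of the aorta that overloads the left ventricle with pressure. PKCδ and PKCε are calcium-independent protein kinase C isoforms encoded by Prkcd and Prkce. The unstressed arm held 4 wild-type, 3 PKCδ, 3 PKCε and 4 combined libraries, and the TAC arm held 4, 3, 4 and 4. Each n below counts libraries. Counts assigned to genes ranged from 10523709 to 17314739 per library, and 13765 of 23420 genes passed the filter on low counts. The lowest chi-square per degree of freedom between replicates of a group was 1.56, between combined unstressed replicates 2 and 4. Other pairs of that group stood at 9.79 to 14.9. Pairs at 2.22 (wild-type unstressed 1 and 4), 2.45 (PKCδ TAC 1 and 2) and 2.53 (PKCε unstressed 1 and 2) were also closer than others of their groups. All lie above sampling noise, which does not exclude that such pairs share a heart. Each library was counted as 1 sample. The labels name unstressed hearts, so the TAC effect includes that of the operation. TAC and unstressed libraries lay apart on the first principal component, which held 31.8% of the variance, and the unstressed combined-ablation libraries lay apart from the other unstressed libraries on the second, which held 12.9%.

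Prkce (GRCm38, chromosome 17, 86167785 to 86657919) was low in the libraries labelled Prkce-null. In unstressed hearts it stood at 49.6 ± 2.48 CPM (counts scaled to library size, mean ± SD, n = 4) in wild type and 43.0 ± 0.63 (n = 3) in PKCδ hearts. It stood at 8.41 ± 0.78 (n = 3) in PKCε hearts and 7.30 ± 0.49 (n = 4) in combined hearts. After TAC it stood at 35.1 ± 8.48 CPM (n = 4), 43.9 ± 0.79 (n = 3), 9.46 ± 1.64 (n = 4) and 15.1 ± 11.0 (n = 4) in the same order. The library labelled combined ablation, TAC, replicate 2 went against its label with 31.5 CPM of Prkce, while the other 3 combined TAC libraries held 8.21 to 11.0 CPM. Wild-type TAC replicate 2 held 24.0 CPM, the lowest of the wild-type libraries, and 10.2 CPM of Myh2, against 0.07 to 0.28 in the other 3 wild-type TAC libraries. Myh2 was singled out here after its values were seen, and RNA of a Prkce-null heart in this library was not tested. Prkcd (GRCm38, chromosome 14, 30595353 to 30626414) was not called against wild type in PKCδ hearts, unstressed (0.21 ± 0.13, log2, SE, adjusted p = 0.38) or after TAC (-0.20 ± 0.13, adjusted p = 0.999). Unstressed wild type held 15.1 ± 1.20 CPM, PKCδ 17.6 ± 1.20, PKCε 18.8 ± 1.14 and combined 14.1 ± 2.27. After TAC the groups held 23.1 ± 3.51, 18.9 ± 1.66, 24.7 ± 0.92 and 20.6 ± 4.12. The labels name no deleted exons and the ablation was cardiac, so whole-gene counts from all cells of the apex do not check the PKCδ label. Per library, Prkce ranged from 46.9 to 52.9 CPM in unstressed wild type, 42.4 to 43.7 in PKCδ, 7.62 to 9.19 in PKCε and 6.59 to 7.69 in combined hearts. After TAC it ranged from 24.0 to 42.9 in wild type, 43.1 to 44.7 in PKCδ and 7.25 to 10.8 in PKCε hearts. All values per library are shown in the plot of Prkcd and Prkce by group.

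**Figure D1:**
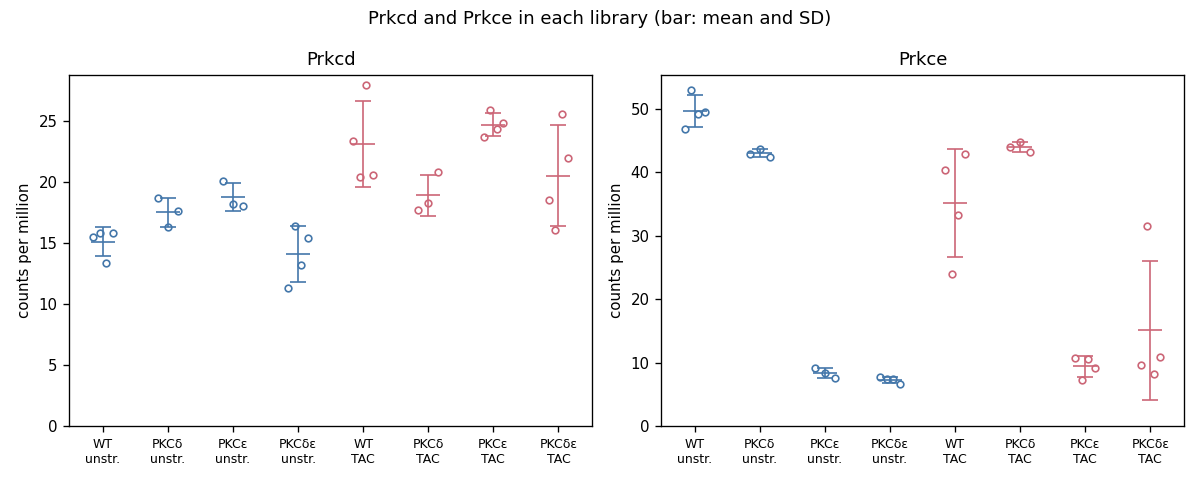
CPM of Prkcd (left) and Prkce (right) in each library (open circles) by genotype and condition (blue unstressed, marked unstr., red TAC), with the group mean and SD as bars. The Prkce-null libraries sit at 6.59 to 11.0 CPM except the library labelled combined ablation, TAC, replicate 2, at 31.5 CPM.

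Transcripts of the sex chromosomes went against many sex labels. Xist, made from the inactive X of females, stood above 5% of its median level in libraries with few or no Y-linked counts in 19 of 23 libraries labelled male, and 11 of these 23 lacked transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at the same threshold. Of 6 libraries labelled female, 4 held Y-linked transcripts. Xist and Y-linked transcripts stood together in 12 libraries, 13 held Xist only and 4 held Y-linked transcripts only. Of the 12, 10 were among the 15 TAC libraries, with all 3 PKCδ ones, and 2 among the 14 unstressed libraries. All unstressed hearts were labelled male, and 10 of these 14 libraries held Xist. The sex label was a term of the fit chosen before the data were examined, and values that move by over 1.5 times without it are given beside the comparisons.

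**Figure D2:**
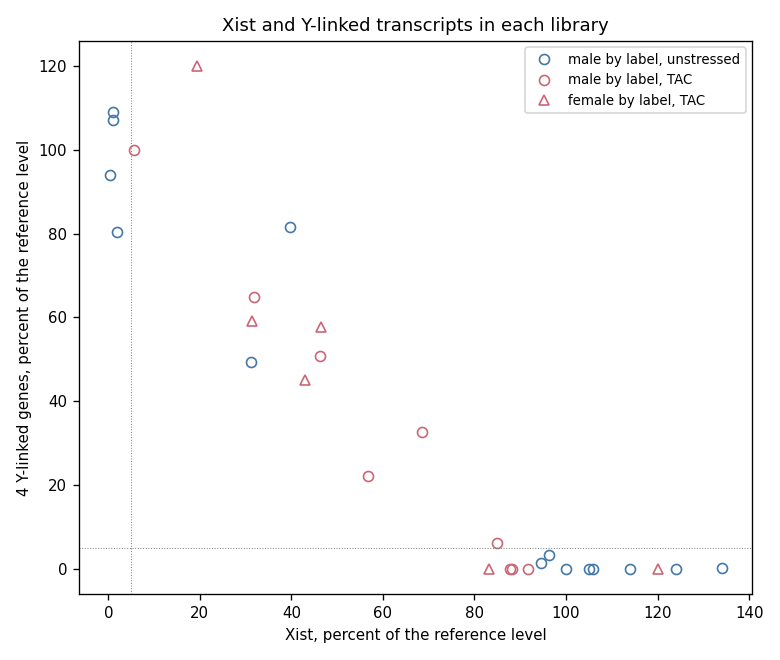
Xist against the summed Y-linked transcripts of each library, both in percent of a reference level (135 CPM for Xist and 54.9 CPM for the Y-linked genes). Circles mark libraries labelled male and triangles libraries labelled female, with unstressed in blue, TAC in red and dotted lines at 5%, and the 12 libraries above both lines hold both kinds of transcript.

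The first comparison asked what TAC changed in wild-type hearts (n = 4 and 4). Genes of cardiac stress and the fetal program rose. Nppa, the atrial natriuretic peptide gene, went from 145.7 ± 9.61 to 1907 ± 394 CPM (SD), a log2 fold change of 3.69 ± 0.47 (SE, adjusted p = 7.4e-06). Its exons overlap an opposite-strand gene over 61.5% of their length, so its counts are uncertain without strand. Myh7, the β-myosin heavy chain gene, rose by 3.61 ± 0.40 (adjusted p = 1.2e-06), Acta1, skeletal α-actin, by 4.55 ± 0.47 (adjusted p = 7.1e-07), and Nppb by 1.74 ± 0.33 (adjusted p = 0.00032). Matrix genes rose with them, among them Col1a1 (1.88 ± 0.25), Postn (2.40 ± 0.42), Cilp (3.94 ± 0.35) and Ltbp2 (4.22 ± 0.45), each with an adjusted p of 0.00017 or lower. Of 44 listed transcripts of ion channels and calcium handling 19 fell and 3 rose, with Kcnj2 at -1.54 ± 0.14 and Kcnd2 at -1.31 ± 0.14 among the lower. So did the ryanodine receptor gene Ryr2 (-0.70 ± 0.08) and the SERCA2 calcium pump gene Atp2a2 (-0.64 ± 0.09). Enzymes of fatty acid oxidation fell as well, among them Acsl1 (-0.71 ± 0.10), Acadm (-0.67 ± 0.10) and Hadha (-0.53 ± 0.08). Ppargc1a, a regulator of mitochondrial genes, fell by -0.80 ± 0.13. In all, 4926 of 13765 genes were called, 2450 higher and 2476 lower, and 668 of these changed at least 2-fold.

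By list, 48 of 53 measured genes of extracellular matrix and fibrosis rose in wild type after TAC and none fell (49 adjusted over the list alone), and 19 of 24 stress and fetal genes rose (19 adjusted over the list alone). In the other direction, 26 of 35 genes of fatty acid oxidation fell and 1 rose (26 and 1 adjusted over the list alone), and 19 of 44 genes of calcium handling and ion channels fell and 3 rose (20 and 3 adjusted over the list alone). The camera test called all 4 lists (adjusted p = 4.5e-29, 1.4e-13, 5.9e-09 and 0.00036), and none held with an estimated correlation (adjusted p = 0.085, 0.085, 0.45 and 0.085 with an estimated correlation). Markers of other cells moved too. Of these, 16 of 25 macrophage and monocyte genes rose (18 adjusted over the list alone, with 1 lower), with C1qa at 0.52 ± 0.08 and C1qb at 0.58 ± 0.09 (camera adjusted p = 7.4e-05; adjusted p = 0.41 with an estimated correlation). Of 18 fibroblast genes 7 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.49 with an estimated correlation). The most abundant gene took 5.63% to 6.17% of counts in wild-type TAC libraries, where it was Rn45s, a pre-ribosomal RNA, in 3 libraries and Myh6 in replicate 2. Rn45s took 11.9% to 14.1% in unstressed ones. Across all genotypes the most abundant gene took 9.9% to 14.1% of counts in unstressed libraries and 4.86% to 8.59% in TAC libraries, without overlap. A technical difference between the arms was not tested and cannot be told apart from TAC. Among genes with the largest falls were Pfkfb1 (-2.36 ± 0.44), a regulator of glycolysis, the clock output gene Hlf (-1.85 ± 0.27) and Cenpf (-1.53 ± 0.17).

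**Figure D3:**
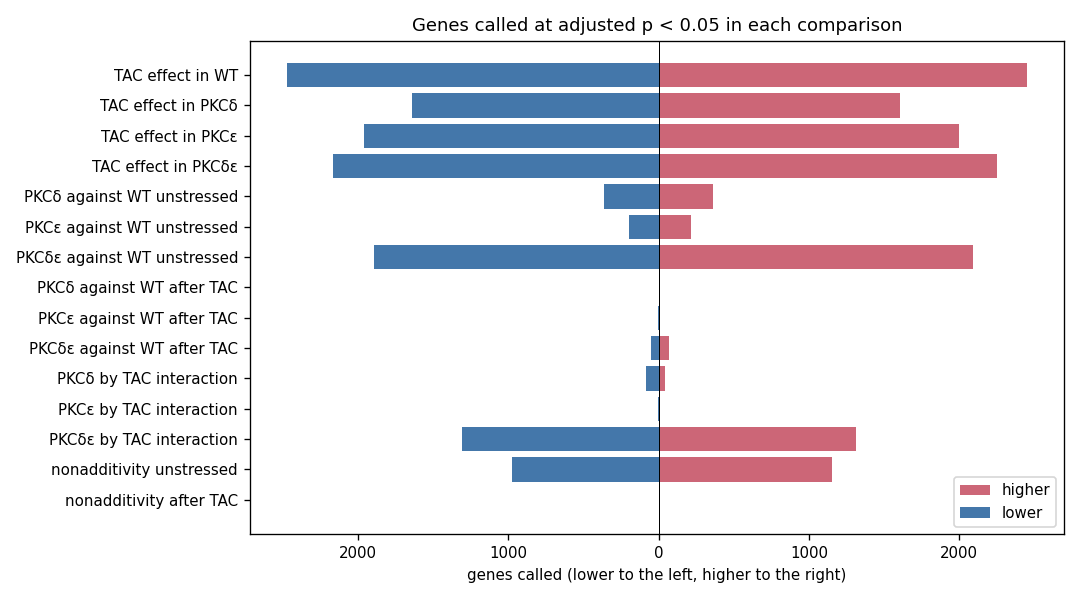
Number of genes called at an adjusted p below 0.05 in each of the 15 comparisons, with genes that were higher to the right in red and genes that were lower to the left in blue. TAC in wild type called 4926 genes, the unstressed combined ablation against wild type 3993, and PKCδ against wild type after TAC 0.

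In PKCδ hearts TAC raised stress and matrix genes (n = 3 and 3). The 3 unstressed libraries held Xist only and the 3 TAC libraries both Xist and Y-linked transcripts, and the sex-linked list had a median log2 fold change of 7.74 here, -7.71 in unstressed PKCδ against wild-type hearts, 8.08 in the PKCδ interaction and 7.26 in the unstressed departure from the sum, with 0 of 5 genes called over all genes or adjusted over the list alone in each. Myh7 rose by 2.75 ± 0.51 (log2, SE, adjusted p = 0.00061), Acta1 by 3.00 ± 0.55 (adjusted p = 0.0006), Ankrd1, a stress-induced myocyte gene, by 2.08 ± 0.42 (adjusted p = 0.0014) and Nppa by 2.68 ± 0.60 (adjusted p = 0.0029). Cilp (3.38 ± 0.43) and Ltbp2 (3.58 ± 0.61) led the matrix genes, while Kcnj5 (-0.93 ± 0.13), Ryr2 (-0.68 ± 0.10) and Cenpf (-2.69 ± 0.22) fell. The test called 3248 genes, 1607 higher and 1641 lower. Of 53 matrix genes 29 rose (34 adjusted over the list alone), and of 24 stress and fetal genes 14 rose (18 adjusted over the list alone). In the other direction 21 of 44 genes of calcium handling and ion channels fell with 2 higher (23 and 2 adjusted over the list alone). Fatty acid oxidation showed 12 of 35 genes lower and 2 higher, with the same numbers adjusted over the list alone. Camera called these 4 lists (adjusted p = 1.5e-13, 1.4e-09, 6.6e-05 and 0.0038), and none held (adjusted p = 0.61, 0.15, 0.089 and 0.86 with an estimated correlation). Among libraries labelled male, which leave 1 PKCδ TAC library whose spread is taken from the other groups, 1600 genes were called. The count was 2094 and 2124 without PKCδ TAC replicate 1 and without PKCδ unstressed replicate 3. Fitted on the 6 PKCδ libraries alone the call of Nppa ended (adjusted p = 0.082).

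In PKCε hearts TAC raised Nppa by 4.79 ± 0.56 (adjusted p = 4.7e-06), Acta1 by 4.34 ± 0.53 (adjusted p = 6.9e-06), and Nppb by 2.40 ± 0.37 (adjusted p = 7.3e-05; n = 3 and 4). Ctgf, a matricellular growth factor gene, rose by 2.35 ± 0.46 (adjusted p = 0.00078). It shares 22.9% of its exonic bases with an opposite-strand gene and is uncertain without strand. Myh7 did not pass the test, at 0.28 ± 0.39 (adjusted p = 0.64), and its mean was 3364 ± 961 CPM before and 4070 ± 1458 after TAC. Postn (2.96 ± 0.47), Cilp (3.88 ± 0.40) and the TWEAK receptor gene Tnfrsf12a (2.54 ± 0.21) rose. Kcnj2 (-1.39 ± 0.14), Hadha (-0.65 ± 0.08), Ech1 (-0.84 ± 0.11) and Bcl2l11 (-1.25 ± 0.14), a pro-apoptotic gene, fell. The test called 3960 genes, 1998 higher and 1962 lower. Of the lists, 22 of 24 stress and fetal genes rose (22 adjusted over the list alone) and 24 of 44 genes of calcium handling and ion channels fell with 1 higher (25 and 1 adjusted over the list alone). Both camera calls held with an estimated correlation (adjusted p = 0.044 and 0.018 with an estimated correlation). Matrix genes rose in 47 of 53 cases (49 adjusted over the list alone) and fatty acid oxidation genes fell in 25 of 35 (28 adjusted over the list alone). These calls did not hold (adjusted p = 0.093 and 0.26 with an estimated correlation). Of 18 fibroblast genes 7 rose and 2 fell, and of 25 macrophage and monocyte genes 6 rose and 0 fell, also when adjusted over the lists alone (camera adjusted p = 0.0070 and 0.010; adjusted p = 0.44 and 0.48 with an estimated correlation). Erythroid and platelet genes rose in 4 of 6 cases (5 adjusted over the list alone; camera adjusted p = 0.049; adjusted p = 0.33 with an estimated correlation), a call that ended without PKCε TAC replicates 1 and 2 or PKCε unstressed replicate 2 (adjusted p = 0.056, 0.062 and 0.090), with the 2 groups alone (adjusted p = 0.17) and with a Y-linked score (adjusted p = 0.066). ERK feedback and immediate early genes, 12 of 27, rose with Etv4 at 2.24 ± 0.47 (14 adjusted over the list alone; camera adjusted p = 0.00015; adjusted p = 0.26 with an estimated correlation). Camera called this list for TAC also in combined hearts, 13 higher and 0 lower (adjusted p = 0.00036), and in wild type, 10 higher and 2 lower (adjusted p = 0.034). Neither held (adjusted p = 0.29 and 0.49 with an estimated correlation).

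In combined-ablation hearts TAC raised Nppa by 6.03 ± 0.56 (adjusted p = 1.4e-07), from 75.2 ± 22.3 to 5140 ± 2406 CPM, and Myh7 by 5.26 ± 0.48 (adjusted p = 1.4e-07). It raised Nppb by 3.33 ± 0.39 (adjusted p = 2.2e-06) and Postn by 3.57 ± 0.46 (adjusted p = 7.4e-06; n = 4 and 4, with the library labelled combined ablation, TAC, replicate 2 among them). Xirp2, an intercalated disc and Z disc protein gene, rose by 2.61 ± 0.17. So did the growth factor genes Tgfb2 and Hbegf by 2.08 ± 0.19 and 2.31 ± 0.23, and the small heat shock protein gene Hspb1 by 1.44 ± 0.16. Lower were the α1A-adrenergic receptor gene Adra1a (-1.99 ± 0.21), Camk2a (-1.28 ± 0.14), Kcnj5 (-1.13 ± 0.12), the T-type calcium channel gene Cacna1h (-2.30 ± 0.40) and Pla2g5 (-2.14 ± 0.21). The test called 4420 genes, 2250 higher and 2170 lower. Stress and fetal genes rose in 20 of 24 cases (22 adjusted over the list alone) and genes of calcium handling and ion channels fell in 19 of 44 with 2 higher (20 and 2 adjusted over the list alone). These calls held (adjusted p = 0.045 and 0.045 with an estimated correlation). Matrix genes rose in 47 of 53 cases (49 adjusted over the list alone), and fatty acid oxidation genes fell in 16 of 35 with 1 higher (20 and 2 adjusted over the list alone). Cell cycle and proliferation genes fell in 17 of 42 with 1 higher (18 and 1 adjusted over the list alone), with Cenpf at -1.67 ± 0.20 and Mcm5 at -1.40 ± 0.24. The 3 lists were called by camera (adjusted p = 1.3e-26, 0.00021 and 7.7e-05) and did not hold (adjusted p = 0.12, 0.50 and 0.50 with an estimated correlation). Of 18 fibroblast genes 12 rose and 1 fell (13 and 1 adjusted over the list alone) and of 18 endothelial genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). Mfap5 stood at 2.32 ± 0.26 and Sox17 at 1.20 ± 0.22 (camera adjusted p = 3.5e-05 and 0.016; adjusted p = 0.24 and 0.29 with an estimated correlation). The count fell to 1015 with the 8 combined libraries fitted alone, where the call of Mcm5 ended (adjusted p = 0.13), and was 2840 among libraries labelled male, which leave 1 combined TAC library whose spread is taken from the other groups and where the endothelial list was not called (adjusted p = 0.061).

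Across all 13765 genes the TAC log2 fold changes of wild type correlated with those of PKCε (Pearson r = 0.719), PKCδ (r = 0.588) and combined hearts (r = 0.523). The genotypes share no library. The TAC effects of wild type, PKCδ and combined hearts do share the sex term of the single fit, so their estimates are not fully separate. Genes are not independent replicates, so no p is given. Of the genes called after TAC in wild type, 2836 were also called in PKCε hearts, 1459 higher in both, 1369 lower in both and 8 in opposite directions. Independent lists of these sizes would share 356 higher and 353 lower. The overlap was 2344 genes for PKCδ, 31 of them opposite, and 2142 for the combined ablation, 180 of them opposite.

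The next comparisons asked what each ablation changed without stress. In unstressed PKCδ hearts (n = 3 against 4 wild type) Fmn1, an actin-nucleating formin gene, was higher by 4.64 ± 0.70 (log2, SE, adjusted p = 0.00053), at 47.5 ± 1.08 against 1.91 ± 0.25 CPM. Also higher were Wdr92 by 2.75 ± 0.38 (adjusted p = 0.00022), Olfml2b by 2.09 ± 0.25 (adjusted p = 5.9e-05) and Ndnf by 2.84 ± 0.51 (adjusted p = 0.0027). Trim12a was lower by -4.61 ± 0.81 (adjusted p = 0.0018), Inmt by -2.95 ± 0.59 and Osgin1 by -1.63 ± 0.26. Trim12a has a close paralog, Trim12c, so its value is uncertain. Genes of the circadian clock moved in both directions. Clock was higher (0.82 ± 0.15) and Wee1 (-1.89 ± 0.34) and Cry1 (-0.92 ± 0.17) lower. Of 19 genes 3 were higher and 4 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.054). Nppa (-0.20 ± 0.47), Myh7 (-0.44 ± 0.40), Acta1 (1.41 ± 0.44) and Col1a1 (0.16 ± 0.26) did not pass the test. The test called 729 genes, 363 higher and 366 lower. The count fell to 235 and 206 without PKCδ unstressed replicates 1 and 3 and to 266 and 383 without wild-type unstressed replicates 1 and 4.

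Unstressed PKCε hearts (n = 3 against 4) held more Myh7, 3364 ± 961 against 187.5 ± 19.4 CPM (4.17 ± 0.41, adjusted p = 9.0e-06), and more of the fast skeletal myosin gene Myh2, at 21.8 ± 7.11 against 0.17 ± 0.09 CPM (adjusted p = 0.0039). Tgm2, tissue transglutaminase, was lower by -1.91 ± 0.17 (adjusted p = 4.0e-07), Arc by -4.13 ± 0.64 (adjusted p = 0.0011). Also lower were Ptk2b, a tyrosine kinase gene, by -1.54 ± 0.23 (adjusted p = 0.00021) and Prkce by -2.56 ± 0.31 (adjusted p = 7.1e-05). Ion channel genes leaned up, with Hcn4 at 1.13 ± 0.22 and Kcnj5 at 0.49 ± 0.10. Of 44 genes 6 were higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 0.0029; adjusted p = 0.28 with an estimated correlation). ERK feedback and immediate early genes leaned down, with a median of -0.40 and 1 of 27 lower (2 adjusted over the list alone; camera adjusted p = 0.00069; adjusted p = 0.32 with an estimated correlation). Endothelial markers leaned down, 3 of 18 lower (7 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.28 with an estimated correlation). The test called 410 genes, 214 higher and 196 lower. The count fell to 106 and 161 without PKCε unstressed replicates 1 and 2 and to 150 and 214 without wild-type unstressed replicates 1 and 4.

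Unstressed combined-ablation hearts differed from wild type in more genes than either single ablation (n = 4 and 4). The cell cycle transcription factor gene E2f1 was higher by 1.65 ± 0.22 (adjusted p = 4.8e-06), and the replication helicase genes Mcm2 by 1.49 ± 0.22 and Mcm5 by 1.38 ± 0.20, from 8.44 ± 0.44 to 22.0 ± 6.86 CPM. The mitochondrial complex III gene Uqcrc2 was lower by -0.70 ± 0.09, from 431.6 ± 36.4 to 265.7 ± 26.9 CPM (uncertain without strand, with 26.6% of its exonic bases shared with an opposite-strand gene). Also lower were the complex I gene Ndufs3 (-0.33 ± 0.06), the fatty acid oxidation gene Hadh (-0.70 ± 0.10) and Ppargc1a (-0.59 ± 0.13, adjusted p = 0.0013). Acta1 was higher by 2.18 ± 0.42 (adjusted p = 0.00073), Cacna1h by 3.39 ± 0.32 (adjusted p = 4.7e-07) and the potassium channel subunit gene Kcne1 by 3.19 ± 0.46. Prkce (-2.77 ± 0.28), Trim12a (-3.59 ± 0.62) and Gpr22 (-1.62 ± 0.24) were lower. Myh7 (-0.03 ± 0.36), Nppa (-0.95 ± 0.44) and Nppb (-0.71 ± 0.32) did not pass the test. The test called 3993 genes, 2095 higher and 1898 lower.

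By list, 17 of 42 cell cycle genes were higher and 0 lower in these hearts (18 and 0 adjusted over the list alone). In the other direction, 18 of 47 genes of oxidative phosphorylation were lower and 0 higher (18 and 0 adjusted over the list alone) and 13 of 35 genes of fatty acid oxidation lower and 0 higher (13 and 0 adjusted over the list alone). Camera called the 3 lists (adjusted p = 2.1e-05, 4.6e-05 and 0.00058), and none held (adjusted p = 0.73, 0.73 and 0.73 with an estimated correlation). Markers of fibroblasts, endothelial cells, smooth muscle and pericytes, and Schwann and neuronal cells were more often lower than higher in the same libraries. Macrophage and monocyte genes were higher in 6 of 25 cases (5 adjusted over the list alone) and lymphocyte genes in 2 of 7 (2 adjusted over the list alone), with 0 lower in either and no camera call (adjusted p = 0.12 and 0.37). Fibroblast genes were lower in 8 of 18 cases and higher in 1, also when adjusted over the list alone, without a camera call (adjusted p = 0.14). Endothelial genes were lower in 11 of 18 cases and higher in 0 (12 and 1 adjusted over the list alone), with Flt1 at -0.60 ± 0.08 and Pecam1 at -0.42 ± 0.07. Smooth muscle and pericyte genes were lower in 9 of 16 with 1 higher (10 and 1 adjusted over the list alone), with Rgs5 at -0.81 ± 0.12 and Steap4 at -1.06 ± 0.14. Schwann and neuronal genes were lower in 6 of 12 with 0 higher (7 and 0 adjusted over the list alone). Camera called these last 3 lists (adjusted p = 4.6e-05, 0.00058 and 0.026), and none held (adjusted p = 0.13, 0.28 and 0.13 with an estimated correlation).

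**Figure D4:**
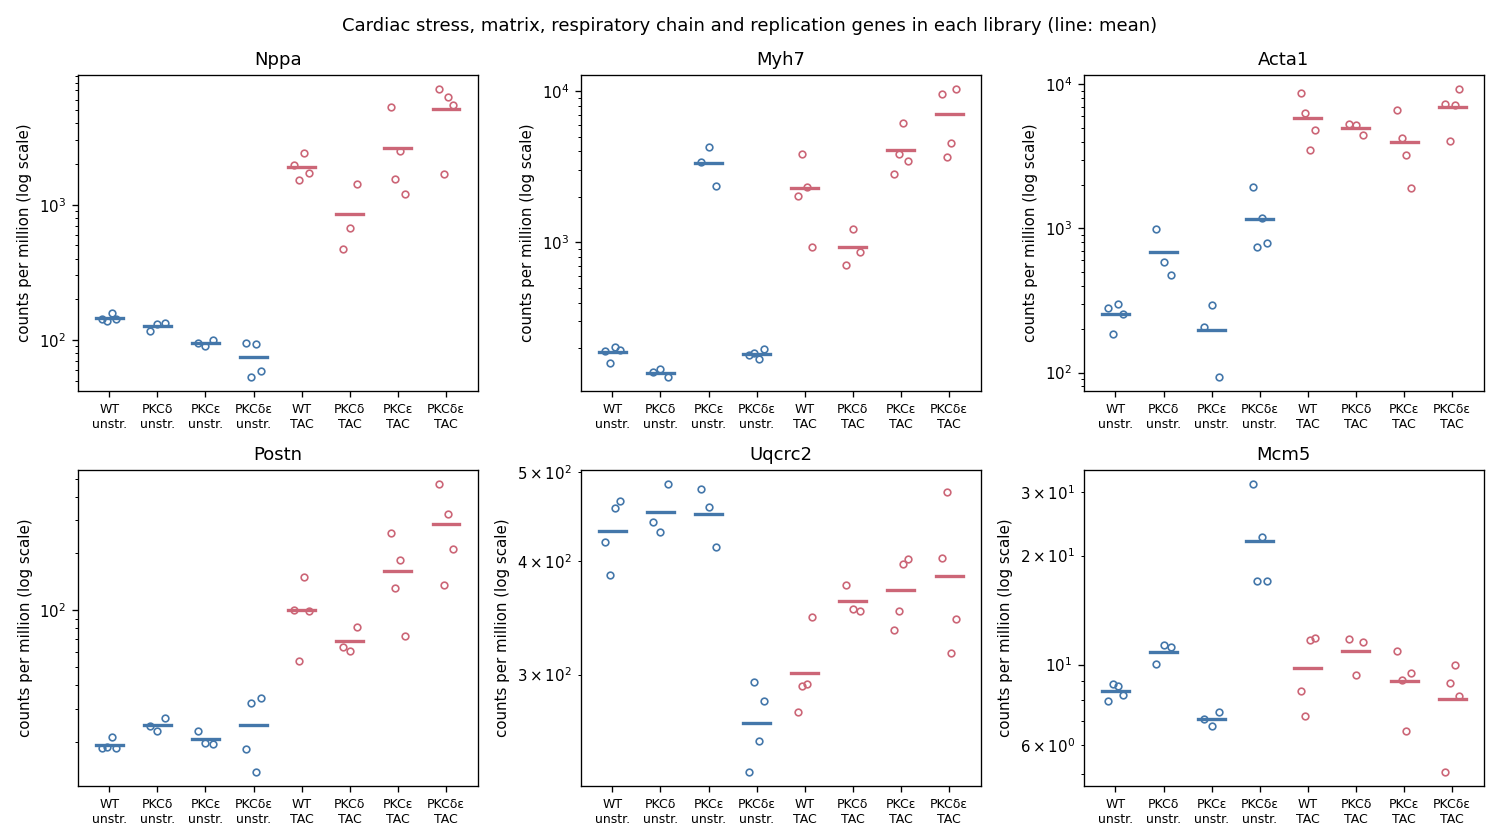
CPM on log axes of Nppa, Myh7, Acta1, Postn, Uqcrc2 and Mcm5 in each library (open circles) by genotype and condition (blue unstressed, red TAC), with lines at the group means. Myh7 stood at 3364 CPM in unstressed PKCε hearts against 187.5 in wild type, and Mcm5 at 22.0 CPM in unstressed combined hearts against 8.44 in wild type.

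After TAC the same genotypes differed from wild type in fewer genes than without stress. In combined hearts the count depended on the sex term, with 122 genes called with it and 930 without it. No gene was called between PKCδ and wild-type hearts (n = 3 and 4) by edgeR, where 482 genes had an unadjusted p below 0.05, nor by DESeq2. Matrix genes stood lower in PKCδ hearts as a group, with a median log2 fold change of -0.41 over 53 genes and 0 called over all genes or adjusted over the list alone, as in Fn1 (-0.62 ± 0.17) and Thbs4 (-1.31 ± 0.47). Macrophage and monocyte genes (median -0.24, C1qa -0.26 ± 0.09), stress and fetal genes (median -0.16, Myh7 -1.30 ± 0.48) and fibroblast genes (median -0.24) leaned the same way, each with 0 called over all genes or adjusted over the list alone. ERK feedback and immediate early genes (median -0.28) leaned down and fatty acid oxidation genes (median 0.10) up, with 0 called in the same 2 ways (camera adjusted p = 0.00026 and 5.7e-05; adjusted p = 0.35 and 0.49 with an estimated correlation). The 4 camera calls of the lists before these (adjusted p = 1.9e-21, 8.6e-07, 0.00053 and 9.4e-05) did not hold (adjusted p = 0.31, 0.31, 0.36 and 0.33 with an estimated correlation). Without PKCδ TAC replicate 1 the stress and fetal, fibroblast and fatty acid oxidation lists were not called (adjusted p = 0.19, 0.19 and 0.26). In simulated data of this design, 41.8% of genes changed 1.5-fold and 80.6% of those changed 2-fold were recovered. The simulation held no sex effect and no spread particular to a gene, so real recovery may be lower.

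In PKCε hearts after TAC (n = 4 and 4), Prkce was lower by -1.78 ± 0.27 (adjusted p = 0.011), and C1qa, a complement gene of macrophages, was lower by -0.41 ± 0.08 (adjusted p = 0.043). Wdr92 was higher by 2.62 ± 0.36 (adjusted p = 0.0055), at 126.5 ± 65.5 against 20.3 ± 6.45 CPM. Tirap (0.61 ± 0.12), Phtf2 (0.41 ± 0.08), Gnpat (0.27 ± 0.05) and 2610507I01Rik made up the 7 genes called, the last of them outside the naming rule and named after its values were seen. Macrophage and monocyte genes were lower as a group, 1 of 25 over all genes and 7 adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.27 with an estimated correlation). So were smooth muscle and pericyte genes, 0 of 16 over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0066; adjusted p = 0.45 with an estimated correlation), a call that ended without wild-type TAC replicate 3 (adjusted p = 0.14) and with the 2 groups alone (adjusted p = 0.062). Myh7 (0.83 ± 0.36), Nppa (0.49 ± 0.43) and Postn (0.67 ± 0.38) did not pass the test. The count was 0 without wild-type TAC replicate 1 (adjusted p = 0.061 for Prkce, Wdr92 and C1qa), 1 without wild-type TAC replicate 3 or PKCε TAC replicate 4, 3 without PKCε TAC replicate 2 or 3, 4 without wild-type TAC replicate 2 and 25 without PKCε TAC replicate 1. It was 46 among libraries labelled male, 79 by DESeq2, 16 without wild-type TAC replicate 2 and the library labelled combined ablation, TAC, replicate 2, 15 with a Y-linked score for the sex label, 24 without these 2 libraries and the sex term, 2 with a replicate block, and 3 both without the filter and with the 2 groups alone, where Wdr92 (adjusted p = 0.22) and C1qa (adjusted p = 0.18) were not called.

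In combined-ablation hearts after TAC (n = 4 and 4), smooth muscle and pericyte genes were lower, 7 of 16 over all genes (11 lower and 1 higher adjusted over the list alone). The pericyte channel gene Kcnj8 stood at -0.57 ± 0.11 and Pdgfrb at -0.37 ± 0.07, and the camera call held (adjusted p = 2.0e-08; adjusted p = 0.039 with an estimated correlation). Xirp2 was higher by 0.87 ± 0.15 (adjusted p = 0.020), Hbegf by 0.86 ± 0.20 (adjusted p = 0.040), Tgfb2 by 0.79 ± 0.17 (adjusted p = 0.027) and Wdr92 by 2.22 ± 0.40 (adjusted p = 0.022). The secreted phospholipase gene Pla2g5 was lower by -1.13 ± 0.19 (adjusted p = 0.020). Stress and fetal genes leaned up, 2 of 24 higher (9 adjusted over the list alone; camera adjusted p = 3.7e-07; adjusted p = 0.28 with an estimated correlation). Macrophage and monocyte genes leaned down, 0 of 25 lower (10 adjusted over the list alone; camera adjusted p = 1.2e-07; adjusted p = 0.21 with an estimated correlation). Nppa (1.39 ± 0.47), Myh7 (1.62 ± 0.46) and Postn (1.54 ± 0.41) did not pass the test. The test called 122 genes, 70 higher and 52 lower. The count became 0 without wild-type TAC replicate 4 (Xirp2 adjusted p = 0.18), 16 and 26 without combined TAC replicates 3 (Xirp2 adjusted p = 0.066) and 1, 26 and 62 without wild-type TAC replicates 2 and 1, 256 without combined TAC replicate 4 and 412 without the library labelled combined ablation, TAC, replicate 2. It was 1 among libraries labelled male, with 1 combined TAC library, 0 with the 2 groups alone, 65 with a replicate block, 307 without that library and wild-type TAC replicate 2, 326 by DESeq2, 930 without the sex term, 712 without the sex term and these 2 libraries, and 1246 with a Y-linked score for the sex label.

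Whether TAC acted differently by genotype was tested as an interaction. In PKCδ hearts, the TAC log2 fold change was below that of wild type for Olfml2b (-2.51 ± 0.36, adjusted p = 0.0018) and Nacad (-2.39 ± 0.32, adjusted p = 0.00032). It was above it for Lonrf1 (1.72 ± 0.28, adjusted p = 0.0018) and Dgat2 (1.49 ± 0.26, adjusted p = 0.0056), a triglyceride synthesis gene. Olfml2b stood higher in unstressed PKCδ hearts, so its value includes that difference. The test called 125 genes, 43 higher and 82 lower. Matrix genes had a median difference of -0.61 over 53 genes, with 1 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 5.9e-11; adjusted p = 0.66 with an estimated correlation). Macrophage and monocyte genes leaned down (median -0.27, 0 of 25 called over all genes or adjusted over the list alone) and endothelial genes up (median 0.17, 0 of 18 over all genes and 1 adjusted over the list alone; camera adjusted p = 0.015 for both; adjusted p = 0.76 and 0.63 with an estimated correlation; 0.58 and 0.22 with fry). Both calls ended without PKCδ TAC replicate 1 (adjusted p = 0.11 and 0.38) and without wild-type TAC replicate 3 (adjusted p = 0.18 and 0.053). Nppa (-1.01 ± 0.70), Myh7 (-0.86 ± 0.61) and Postn (-0.89 ± 0.63) did not pass the test. The count was 12 and 68 without PKCδ TAC replicates 1 (Dgat2 adjusted p = 0.063) and 2, 76 and 65 without PKCδ unstressed replicates 1 and 3, and 72 without wild-type TAC replicate 4, against 237 by DESeq2, 401 with the 4 groups alone and 199 with a Y-linked score for the sex label.

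In PKCε hearts the interaction called 4 genes, 1 higher and 3 lower, among them Tgm2 at 1.34 ± 0.21 (adjusted p = 0.014), with Myh7 (-3.34 ± 0.53, adjusted p = 0.017) and Heatr5b (-0.82 ± 0.15, adjusted p = 0.019) lower. Heatr5b lies within 20 Mb of Prkce, where DNA of another strain beside the targeted gene stays open. Myh7 stood at 187.5 and 2293 CPM in unstressed and TAC wild-type hearts and at 3364 and 4070 CPM in PKCε hearts. The count was 0 without PKCε unstressed replicate 1 (Myh7 adjusted p = 0.055), 2 without PKCε TAC replicate 1 (Myh7 adjusted p = 0.065), wild-type unstressed replicate 1 or wild-type unstressed replicate 4, 8 without PKCε TAC replicate 2 or wild-type unstressed replicate 3, 20 without PKCε unstressed replicate 3 and 23 without wild-type unstressed replicate 2. It was 45 by DESeq2, 11 with a replicate block, 14 with a Y-linked score for the sex label, and 8 both without the sex term, wild-type TAC replicate 2 and the library labelled combined ablation, TAC, replicate 2, and with the 4 groups alone, where Heatr5b was not called (adjusted p = 0.077), as without wild-type TAC replicate 3 (adjusted p = 0.084) or PKCε TAC replicate 3 (adjusted p = 0.073).

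In combined hearts the interaction called 2623 genes, 1311 higher and 1312 lower. Against wild type these hearts differed in 3993 genes unstressed and 122 after TAC (930 without the sex term). Mcm5, Mcm2, E2f1 and Cacna1h stood higher and Uqcrc2 lower in unstressed combined hearts. Their values below include that difference and do not show a separate one after TAC. The TAC log2 fold change was lower than in wild type for Mcm5 (-1.64 ± 0.29, adjusted p = 0.00051), Mcm2 (-1.77 ± 0.32) and E2f1 (-1.62 ± 0.33). Of 42 cell cycle genes 15 were lower and 0 higher (16 and 0 adjusted over the list alone; camera adjusted p = 4.6e-06; adjusted p = 0.68 with an estimated correlation). Uqcrc2 was at 0.96 ± 0.14 (adjusted p = 7.8e-05). Of 47 oxidative phosphorylation genes 8 were higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.0093; adjusted p = 0.79 with an estimated correlation). Macrophage and monocyte genes were lower in 10 of 25 cases (11 adjusted over the list alone), with Csf1r at -0.74 ± 0.12 and C1qc at -0.80 ± 0.13. Endothelial genes were higher in 5 of 18 (6 adjusted over the list alone), with Flt1 at 0.66 ± 0.12 (camera adjusted p = 8.1e-05 and 0.035; adjusted p = 0.68 and 0.68 with an estimated correlation). Hbegf (1.71 ± 0.29, adjusted p = 0.00042), Nppa (2.34 ± 0.64, adjusted p = 0.015) and Ctgf (2.12 ± 0.60, adjusted p = 0.019) rose more than in wild type, and Cacna1h (-3.41 ± 0.48, adjusted p = 0.00014) was lower. The Nppa call ended without combined TAC replicate 3 (adjusted p = 0.10) or wild-type TAC replicate 4 (adjusted p = 0.055). The Ctgf call ended without the latter (adjusted p = 0.084), among libraries labelled male (adjusted p = 0.15) and with the 4 groups alone (adjusted p = 0.078). The oxidative phosphorylation and endothelial lists were not called among libraries labelled male, with 1 combined TAC library (adjusted p = 0.32 and 0.058), or without wild-type TAC replicate 3 (adjusted p = 0.065 for both). The endothelial list was also not called with the 4 groups alone (adjusted p = 0.058) or without combined TAC replicate 4 (adjusted p = 0.076) or combined unstressed replicate 1 (adjusted p = 0.064). The count was 1595 without wild-type TAC replicate 4, 910 among libraries labelled male and 1505 with the 4 groups alone.

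The last comparison asked whether the combined ablation departed from the sum of the single ablations on the log scale. In unstressed hearts it called 2125 genes, 1151 higher and 974 lower. Myh7 departed by -3.75 ± 0.55 (adjusted p = 0.00052), with means of 187.5 CPM in wild type, 137.9 in PKCδ, 3364 in PKCε and 183.3 in combined hearts. Wdr92 (-3.10 ± 0.52, adjusted p = 0.0013) and Gpr22 (-2.07 ± 0.34, adjusted p = 0.00059) departed downward too. Arc (3.63 ± 0.79, adjusted p = 0.0057), C1qa (0.92 ± 0.12, adjusted p = 4.0e-05) and Uhrf1 (1.43 ± 0.32, adjusted p = 0.0045), a gene of DNA methylation upkeep, departed upward. Cell cycle genes were higher in 9 of 42 cases and lower in 1 (10 and 1 adjusted over the list alone). Fatty acid oxidation genes were lower in 8 of 35 and higher in 2 (13 and 2 adjusted over the list alone) and interferon response genes lower in 5 of 32 and higher in 0 (5 and 0 adjusted over the list alone), with Gbp4 at -1.50 ± 0.28. Camera called the 3 lists (adjusted p = 0.00022, 0.0028 and 0.00022), and none held (adjusted p = 0.93, 0.93 and 0.93 with an estimated correlation). The count fell to 988 without PKCδ unstressed replicate 3 and to 1025 without PKCε unstressed replicate 1.

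After TAC no gene departed from the sum of the single ablations by edgeR, where 1294 genes had an unadjusted p below 0.05, while DESeq2 called 28. As a group, stress and fetal genes departed upward, 0 of 24 over all genes and 10 adjusted over the list alone, with Myh7 at 2.09 ± 0.54 and Nppa at 2.11 ± 0.63. The group of calcium handling and ion channel genes departed downward, 0 of 44 over all genes and 3 adjusted over the list alone, with Kcnd2 at -0.89 ± 0.20 and Atp2a2 at -0.55 ± 0.13. Both camera calls held (adjusted p = 8.2e-15 and 4.5e-07; adjusted p = 0.032 and 0.019 with an estimated correlation). Matrix genes leaned up, 0 of 53 over all genes and 25 adjusted over the list alone, with Thbs4 at 2.24 ± 0.55 (camera adjusted p = 2.1e-27; adjusted p = 0.080 with an estimated correlation). Fatty acid oxidation genes leaned down, 0 of 35 over all genes or adjusted over the list alone, with a median of -0.29 (camera adjusted p = 9.0e-13; adjusted p = 0.22 with an estimated correlation). The count of genes was 139 without the library labelled combined ablation, TAC, replicate 2, 105 without it and wild-type TAC replicate 2, 188 without both and without the sex term, 27 without PKCε TAC replicate 1, 1 without wild-type TAC replicate 4 and 1 among libraries labelled male, with 1 PKCδ and 1 combined TAC library.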

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

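The tests of sex labels, of admixture and of the share of other cells were chosen after the result was seen, as was a subset of 6 marker genes.

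Prkce in the library labelled combined ablation, TAC, replicate 2 stood at 31.5 CPM, against 11.0 in the nearest of its group. A candidate explanation is a wrong genotype label on a heart with intact Prkce. Over 32 genes called at least 2-fold in both Prkce-null genotypes without stress, its median position was -0.004, where 0 is the mean of wild-type and 1 that of PKCε TAC libraries. The ranges of Prkce-intact libraries (-0.368 to 0.617) and Prkce-null libraries (0.191 to 1.395) overlap, and this stays open. Over the subset of 6 genes it stood at 0.237, against -0.713 to 0.385 and 0.83 to 1.49. The 6 were picked from the 32 because they differed at least 2-fold between wild-type and PKCε TAC libraries. The gap between the ranges is therefore partly built in, and the subset decides nothing. No biological explanation was tested.

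Xist and Y-linked transcripts stood together in 12 libraries, and 10 at a threshold of 10% of the reference. A wrong sex label on a library of a single heart is argued against for these 12. RNA from a heart with intact Prkce is argued against by the level of Prkce for 4 Prkce-null libraries with a minor share of 10% or more. Libraries with a smaller minor share and the library labelled combined ablation, TAC, replicate 2 were not covered. In the 4 libraries Prkce stood at a mean of 9.26 CPM against 19.2 needed, a shortfall of 9.93. The SD was 0.962 over 8 single-sex Prkce-null libraries, taken about the means of unstressed and TAC libraries and without the library labelled combined ablation, TAC, replicate 2. Pooling of hearts of the same genotype or RNA carried over between such libraries may remain and was not tested. No biological explanation was tested.

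The combined ablation differed from wild type in 3993 genes unstressed and 122 after TAC. With a Y-linked score for the sex label the counts were 4103 and 1246, and without the sex term 4023 and 930. The ratio of 3.29 with the score argues against sex composition as the whole cause. The count after TAC moved with the handling of sex, so a part of it stays open. A correction for GC content and gene length over 13660 genes gave 3621 and 27 genes, which argues against these as the whole cause. Unstressed, 2725 genes were called both with and without the correction. Across genes, r of the unstressed log2 fold change with GC content was 0.268, so a part in single calls stays open. A lower share of cells other than cardiomyocytes stays open. Medians were -0.30 for endothelial, -0.23 for fibroblast, -0.40 for smooth muscle, 0.13 for macrophage and -0.76 for Schwann genes, a difference of 0.889 between the highest and the lowest that lies within their spread. A partial pressure-overload response, which the design names, may also remain. Across genes r with the TAC effect of PKCε hearts was 0.185 (Spearman 0.173; genes are not independent). Of the genes, 847 of 1268 genes called in both, 66.8%, went the same way. The larger spread of TAC libraries was not tested as a cause.

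Among 90 groups of 4 libraries tested over 18 measures, 10 held a library far from the other 3, and chance gives about 1 in 20 groups. These were in CPM Prkcd at 13.4, Postn at 21.1 and Cpt1b at 12.8 in wild-type unstressed replicate 3. Cpt1b shares 94.8% of its exonic bases with a gene on the same strand, and its counts are uncertain. The others were Nppb at 543 in wild-type TAC replicate 2, Col3a1 at 1690 in wild-type TAC replicate 3, Atp2a2 at 9110 in wild-type TAC replicate 4, Atp2a2 at 9910 and Mki67 at 15.6 in combined unstressed replicate 1, Pdk4 at 993 in combined unstressed replicate 3, and Prkce as above.

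The TAC effect differed from that of wild type in 125 genes for PKCδ, 4 for PKCε and 2623 for combined hearts. Of the genes fixed in advance this held for Myh7 in PKCε hearts (-3.34) and in combined hearts for Prkce (1.29), Nppa (2.34), Nppb (1.59), Acta1 (-1.83), Ctgf (2.12) and Ppargc1a (0.70). The Prkce value includes the library labelled combined ablation, TAC, replicate 2, at 31.5 CPM. It also includes the lower wild-type mean after TAC, 35.1 CPM against 49.6 CPM unstressed. Outside the gene counts, reads aligned to more than 1 place took a median of 11.4% in TAC libraries against at most 9.57% in unstressed ones.

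As a check on chance, libraries were split in other ways into groups of the same sizes. For the TAC effect 1 of 35 splits, the real one, gave as many genes in wild type (4926, highest other 688), PKCε (3960, 2213) and combined hearts (4420, 562), a share under 0.05. It is also the smallest share that 35 splits can give, and no allowance was made for the number of comparisons. The 10 splits of PKCδ hearts are too few for a share under 0.05 (3248, highest other 0). Unstressed, 1 of 35 splits did so for PKCδ (729, 384), PKCε (410, 241) and combined hearts (3993, 539), again a share under 0.05. Without PKCδ unstressed replicate 3 the PKCδ count was 206, and without PKCε unstressed replicate 1 the PKCε count was 106. Both lie below the highest other counts of their splits. After TAC, 1 of 35 did so for PKCε (7, highest other 1), 2 of 35 for combined hearts (122, highest other 249), where chance was not excluded. For PKCδ the count of 0 was reached by all 35 by construction, which decides nothing, with a highest other of 0 by edgeR, 482 at an unadjusted p below 0.05 in the real split and 0 by DESeq2. Of 60 splits drawn, 1 gave as many for the PKCδ interaction (125, highest other 2), 2 for the combined interaction (2623, highest other 2853) and 1 for the unstressed departure from the sum (2125, highest other 1437), shares under 0.05. These splits exchanged the genotypes compared within each condition, and so also broke up the genotype differences within a condition, such as the 729 genes for unstressed PKCδ. The shares therefore do not single out an interaction or a departure from the sum. Up to sign, the split with 2853 kept the unstressed groups as they are and exchanged wild-type TAC replicate 1 with combined TAC replicate 4. The combined count therefore does not show a difference in the TAC arm apart from the unstressed difference. For the PKCε interaction 3 of 60 did so (4, highest other 93), chance was not excluded, and a split with many times the real count points to a structure of the samples, whose cause was not tested. For the departure from the sum after TAC the count was 0 by edgeR, with 1294 genes at an unadjusted p below 0.05 and 28 by DESeq2. It was reached by 60 of 60 splits by construction, which decides nothing (highest other 382).

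DNA of another strain beside a targeted gene may contribute to calls. Within 20 Mb of Prkce, 6 of 94 genes were called in unstressed PKCε hearts (odds ratio 2.24, 95% interval 0.796 to 5.12, exact Fisher p = 0.061) and 0 of 94 after TAC (odds ratio 0). Heatr5b, also called in the PKCε interaction, was among the 6. Within 20 Mb of Prkcd 11 of 167 in genes were called in unstressed PKCδ hearts (odds ratio 1.26, 0.613 to 2.33, exact Fisher p = 0.48). The intervals leave this open.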

How the results depend on the processing

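The score of Y-linked transcripts and leaving out the library labelled combined ablation, TAC, replicate 2 and wild-type TAC replicate 2, with or without the sex term, were chosen after seeing the data. RLE normalization moved no count of called genes by over 1.5 times, and where a count moved the cause was not tested, except that fewer libraries enter some fits. Among libraries labelled male, which leave 1 PKCδ and 1 combined TAC library assumed to vary like the other groups, the count was 1600 for the TAC effect in PKCδ and 2840 in combined hearts, 46 for PKCε and 1 for combined hearts against wild type after TAC, 910 for the combined interaction and 1 for the departure from the sum after TAC. With only the groups compared it was 1015 for the TAC effect in combined hearts, 3 and 0 for PKCε and combined hearts after TAC, and 401, 8 and 1505 for the PKCδ, PKCε and combined interactions. DESeq2 gave 79 and 326 for PKCε and combined hearts after TAC, 237 and 45 for the PKCδ and PKCε interactions and 28 for the departure from the sum after TAC. A Y-linked score gave 15 and 1246 for PKCε and combined hearts after TAC and 199 and 14 for the PKCδ and PKCε interactions. Without the 2 libraries it was 16, 307 and 105 for PKCε and combined hearts after TAC and the departure from the sum after TAC, and without the sex term as well 24, 712 and 188, with 8 for the PKCε interaction. Without the sex term alone combined hearts after TAC gave 930, and without the filter PKCε hearts after TAC gave 3. Replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.134 to 0.181, and at most 2 best with their own number), and the replicate block gave 2 and 65 for PKCε and combined hearts after TAC and 11 for the PKCε interaction.

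Leaving out each library in turn gave 4068 to 4787, 2094 to 2984, 2703 to 3819 and 3038 to 4604 genes for the TAC effect in wild type, PKCδ, PKCε and combined hearts. It gave 206 to 750, 106 to 487 and 2878 to 3936 unstressed for PKCδ, PKCε and combined hearts, and 0 to 0, 0 to 25 and 0 to 412 after TAC. It gave 12 to 176, 0 to 23 and 1595 to 3009 for the interactions, and 988 to 2370 and 0 to 139 for the departure from the sum unstressed and after TAC. The 0 for PKCδ after TAC is by edgeR, with 482 genes at an unadjusted p below 0.05 with all libraries and 0 by DESeq2. The oxidative phosphorylation list, called by camera as higher in PKCδ hearts after TAC (adjusted p = 0.64 with an estimated correlation), turned direction without PKCδ TAC replicate 1 (adjusted p = 0.84, with a range of 6.2e-10 to 0.84 over libraries left out). The sarcomere and Z disc list, called as higher in combined hearts after TAC (adjusted p = 0.52 with an estimated correlation), turned among libraries labelled male, with 1 combined TAC library (adjusted p = 0.77), and the cause was not tested. With the Y-linked score, which contains them, Y-linked genes turned direction. Kdm5d, Uty and Eif2s3y turned to 1.80, 1.74 and 2.48 for the TAC effect in wild type, Kdm5d and Uty to 1.48 and 1.56 in unstressed combined hearts, and Ddx3y to -3.25 for the combined interaction. Of 98 list calls 7 held with an estimated correlation and 51 with fry. With genes of mean log2 CPM of at least 2, r of the TAC effects with wild type was 0.648, 0.792 and 0.582 for PKCδ, PKCε and combined hearts. Depth limits the genes of few counts, and 2-fold changes were recovered in simulated data at 71.6% for the PKCδ interaction and 64.2% for the departure from the sum after TAC, and 1.5-fold changes at 23.9% and 22.4%. These rates hold for the simulated spread, and real recovery may be lower.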

Other observations

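The Y-linked score and the fit without 2 libraries were chosen after seeing the data. In wild-type hearts after TAC the clock output gene Nr1d2 (-1.42 ± 0.15, log2, SE) and Hlf (-1.85 ± 0.27) fell and Arntl, a core clock gene, rose (2.93 ± 0.56). In all, 10 of 19 circadian genes were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.45 with an estimated correlation; n = 4 and 4). The camera call was lost without wild-type TAC replicate 1 (adjusted p = 0.051). The list's median log2 fold change with TAC was -0.45 in wild type and 0.18, 0.01 and -0.06 in PKCδ, PKCε and combined hearts, and against unstressed wild type it was -0.60, -0.30 and -0.28 in the unstressed hearts of the same genotypes, without a camera call in the 6 comparisons outside the TAC effect in wild type. Tested as an interaction, camera called the list as higher in PKCδ hearts, with 1 of 19 genes higher and 0 lower (10 and 3 adjusted over the list alone), and in PKCε hearts, with 0 higher and 0 lower (5 and 3 adjusted over the list alone). The camera adjusted p values were 0.0025 in PKCδ and 0.0084 in PKCε hearts (0.59 and 0.49 with an estimated correlation), without a call in combined hearts (adjusted p = 0.10). The PKCε call ended without PKCε TAC replicate 1 (adjusted p = 0.055) and PKCε unstressed replicate 2 (adjusted p = 0.093), each left out alone. The time of day of collection is not given in the sources used here.

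In combined hearts after TAC, chaperone and unfolded protein response genes rose in 12 of 29 cases and fell in 2 (12 and 3 adjusted over the list alone), with Atf4 at 0.76 ± 0.09. The p53 and apoptosis genes rose in 12 of 23 and fell in 2 (14 and 2 adjusted over the list alone), with Tnfrsf12a at 2.34 ± 0.21. Camera called both (adjusted p = 0.013 for each; adjusted p = 0.43 and 0.29 with an estimated correlation; n = 4 and 4). The first camera call was lost without the sex term (adjusted p = 0.11), also with wild-type TAC replicate 2 and the library labelled combined ablation, TAC, replicate 2, left out (adjusted p = 0.14), and with a Y-linked score (adjusted p = 0.14). The p53 and apoptosis list was also called for TAC in PKCε hearts, with 9 of 23 genes higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.0030; adjusted p = 0.22 with an estimated correlation).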
